A study of Mus musculus with 17 samples.

How the data were processed

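Gene expression was measured in 5 progenitor fractions sorted by flow cytometry from the bone marrow of adult mice, on 17 Affymetrix 3-prime expression arrays. Cells came from mice aged 10 to 14 weeks, per the labels. The labels do not say whether the arrays of a fraction came from separate mice or sorts, so p-values measure only the spread between these arrays, which may be technical. Each array was put in its fraction by the gate in its title, which also gives the replicate number. The free-text description of all 17 arrays names another gate, which conflicts with the titles and was not used. The short names CLP, preGM, MkP and preCFUE follow the study's scheme from general knowledge, and the name preMegE stands in the design text.

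The upstream steps are known only from the labels and the design text. Cells were sorted into lysis buffer and RNA was isolated on spin columns, per the labels' protocols. RNA was amplified in more than 1 round of in vitro transcription with a small-sample protocol, and chips were scanned and scaled to a common median, per the series' design text. The deposited values are RMA intensities on a linear scale, 1 per probe set and array, with RMA named both in the design text and in the submitters' processing notes. The RMA version and software are not given in the sources used here. Scaling of arrays was not visible in the deposited probe set values, whose medians ran from 16.0 to 19.1. The design text also names dChip software with a filter on the ratio of SD to mean above 0.5. That filter had not been applied to the deposited table, which held all 45101 probe sets, and it was tried here as an alternative. Second-round amplification shortens RNA toward its 3-prime end and can vary between samples, so the ratio of 3-prime to 5-prime control probe sets was computed for each array.

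Probe sets were named through the platform annotation table. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and were not named, 64 were controls and left out (some of these also carry a symbol and are counted under both), and 9160 others were not listed in that table and are unnamed here. By gene identifier, 34754 of the 34958 were found in the RefSeq table of assembly GRCm38.p6, and 0 symbols changed. That table served for names and for membership of the X and Y chromosomes, and no coordinates are given because no source names a genome build for the array values. For each gene the probe set with the highest mean was used, which mattered for 9010 genes with several, and left 18193 genes. A probe set of a named gene that passed the test in the opposite direction is stated beside it.

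Values were taken as log2(intensity + 16), so a log2 fold change on this scale understates the change of dim genes. Of all values, 47.3% lay under 16, and 6025 genes had a mean under 16. The lowest value was 4.33 and the highest 24739. No background level per probe set was given, so a dim value is not evidence of absence, and the number of arrays limits the precision. All 17 arrays entered 1 linear model with a term per fraction in limma 3.58.1 (lmFit, contrasts and eBayes, with 12 residual and 2.01 prior degrees of freedom) under R 4.3.3. Tables were read with data.table version 1.17.8, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15. P-values were adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 counts as passing the test. The 5 comparisons were preMegE against preGM, MkP and preCFUE each against preMegE, MkP against preCFUE, and CLP against preGM, with a moderated F test over all fractions.

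Before the data were examined, 24 gene lists were fixed, together with the comparisons, the alternatives and the rule for named genes. The lists covered the genes used in the sort, lymphoid, granulocyte and monocyte, erythroid, heme and iron, and megakaryocyte and platelet genes, myeloerythroid regulators and stem or multipotent genes. They also covered cytokine receptors, S phase, G2 and M phase, ribosome biogenesis, interferon response, MHC class II, immediate-early and sex-linked genes. Another 8 lists held markers of other cells: mature B and plasma cells, T and NK cells, neutrophils, macrophages, mast cells and basophils, eosinophils, dendritic cells, and endothelium and stroma. Each list was tested with camera at its preset correlation of 0.01, adjusted over 120 tests (24 lists in 5 comparisons), and again with the correlation estimated per list. Members past the test were counted over all genes and adjusted over the list alone.

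Named genes were the sort genes, and per comparison the 5 largest rises and the 5 largest falls among genes past the test whose arrays did not overlap. From each list a comparison is about, the 4 members with the largest change past the test and up to 2 abundant members that did not pass were added. From any other list called by camera, the 2 members with the largest change past the test were added. Sex-linked genes and a few others, named as such, were chosen after their values were seen.

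Settings chosen in advance to be varied were centring each array on its median, quantile normalization, a filter at the 40th percentile of mean level, the SD over mean filter, the mean over a gene's probe sets, and a test over all probe sets. Further ones were a trended and robust prior, array weights, a fit of only the arrays compared, the replicate number as a block, a requirement of at least 2-fold change, and leaving out each array in turn. A pseudocount of 16, also listed in advance as a variation, is identical to the values used. Added after the data were seen were log2 without a pseudocount, the 3-prime over 5-prime ratio as a covariate, and the mean of the neutrophil markers as a covariate. Principal components were computed over the tested genes.

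The steps were tested on simulated arrays with 200 of 18193 genes changed per comparison, 50 at each of 4 sizes. Changes were planted only in genes brighter than the median gene, as shifts on the transformed scale used for the tests. Recovery among dimmer genes was not tested, so the shares below do not apply to them. The same fold change of raw intensity is a smaller shift on that scale, so its recovery may be lower than given here. For preMegE against preGM, MkP against preMegE, preCFUE against preMegE, MkP against preCFUE and CLP against preGM, 48%, 52%, 56%, 46% and 44% of genes changed 2-fold were recovered. Over these comparisons the share ran from 10% to 22% at 1.5-fold, from 86% to 100% at 4-fold and from 96% to 100% at 8-fold. Of 17993 unchanged genes, 2, 5, 11, 15 and 5 were called in the same order, which made 1.61%, 3.65%, 7.38%, 10.3% and 3.82% of the calls false. Every simulated array had the same spread per gene, whereas array weights in the data ran from 0.32 (CLP replicate 2) to 5.52 (preGM replicate 2). The shares recovered and false may therefore not hold in the data, above all for CLP against preGM. A planted list of 20 genes was called in all 5 comparisons, and 0 of the 24 other lists were. Simulated genes were drawn independently, so this does not test list calls where members vary together. In the data the estimated correlation reached 0.521 (ribosome biogenesis).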

Results

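Transcript levels were compared among 5 fractions of mouse bone marrow that stand near the branch points of blood cell formation. The CLP fraction (Lin-Sca1lowKitlowIL7r+Flk2+, 3 arrays) holds common lymphoid progenitors. The other 4 fractions lie in the Kit+ Sca1- myeloid compartment and were split by Itga2b, Slamf1 and Eng, with 3 of them also gated as low for the Fc gamma receptors. They were preGM, directed to granulocytes and monocytes (Slamf1-Englow, 3 arrays), preMegE, the shared precursor of megakaryocytes and red cells (Slamf1+Englow, 5 arrays), preCFUE, an early erythroid stage (Slamf1+Enghigh, 3 arrays), and MkP, megakaryocyte progenitors (Itga2b+Slamf1+, 3 arrays). Values are RMA intensities, given as mean ± SD over n = 5 arrays for preMegE and n = 3 arrays for each other fraction. Fold changes are on the log2(intensity + 16) scale with ± their SE, and adjusted p-values come from limma. Each gene is given by 1 probe set, and with the mean over its probe sets instead, 56 of 189 named changes that passed moved in size by over 1.5 times.

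Of 18193 genes, 6345 (34.9%) differed among the fractions by the F test. Correlations between arrays of a fraction ran from 0.964 to 0.996 in preGM, 0.974 to 0.993 in preMegE, 0.979 to 0.985 in MkP and 0.985 to 0.990 in preCFUE. In CLP they ran from 0.940 to 0.960. Between fractions the mean correlation was highest for preMegE and preCFUE (0.964) and lowest for CLP and preCFUE (0.866). CLP replicate 2 correlated better with the preGM arrays (0.961) than with the other CLP arrays (0.949), and was the 1 array of the 17 closer to another fraction than to its own. The Gapdh 3-prime over 5-prime log2 ratio, which rises as RNA is shortened, was 4.07 ± 1.06 in CLP, 3.27 ± 0.62 in preGM, 3.58 ± 0.56 in preMegE, 3.85 ± 0.41 in MkP and 3.49 ± 0.62 in preCFUE. Within CLP it was 5.12 in replicate 1, 3.00 in replicate 2 and 4.08 in replicate 3. The 75th percentile of intensity ran from 50.6 to 74.4 over the arrays.

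**Figure D1:**
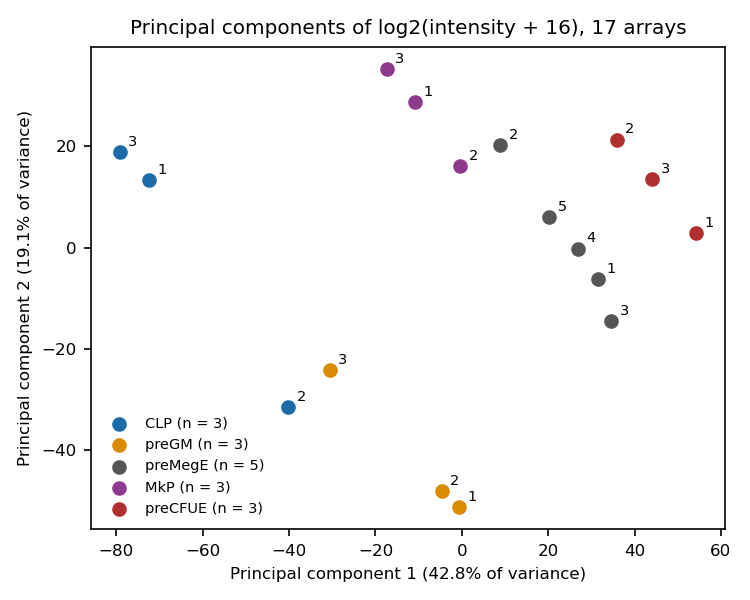
Principal components of the 17 arrays over 18193 genes, with component 1 (42.8% of variance) on the horizontal and component 2 (19.1%) on the vertical axis, 1 point per array coloured by fraction. CLP replicates 1 and 3 lie at -72.4 and -79.1 on component 1, while CLP replicate 2 at -40.2 lies nearest to preGM replicate 3 at -30.6.

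The genes behind the sort showed which gates were visible in the transcripts. Il7r was 1752 ± 553 in CLP, 60.5 ± 39.2 in preGM and 12.5 ± 1.45 in preMegE. Flt3, which encodes Flk2, was 2118 ± 398 in CLP and 1090.1 ± 50.5 in preGM against 49.9 ± 12.2 in preMegE. Kit, the stem cell factor receptor used in the gate of every fraction, was 110.4 ± 54.8 in CLP, 185 ± 57.4 in MkP and 681 ± 180.2 in preMegE. Itga2b, the platelet integrin chain that defines MkP, was 2058 ± 249 there, 319 ± 64.2 in preMegE and 62.5 ± 3.91 in preCFUE. Slamf1 was 101 ± 13.2 in preMegE, 58.6 ± 7.19 in MkP, 20.4 ± 1.89 in preCFUE and 10.6 ± 1.75 in preGM. It was lower in preCFUE than in preMegE (log2 fold change -1.68 ± 0.094, adjusted p = 1.06e-07) although both gates are Slamf1+. Eng was 237 ± 44.2 in preCFUE and 234 ± 16.2 in preMegE, although the gates are Enghigh and Englow (log2 fold change 0.0059 ± 0.14, adjusted p = 0.996). The sign of that Eng difference turned under quantile normalization (-0.072).

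**Figure D2:**
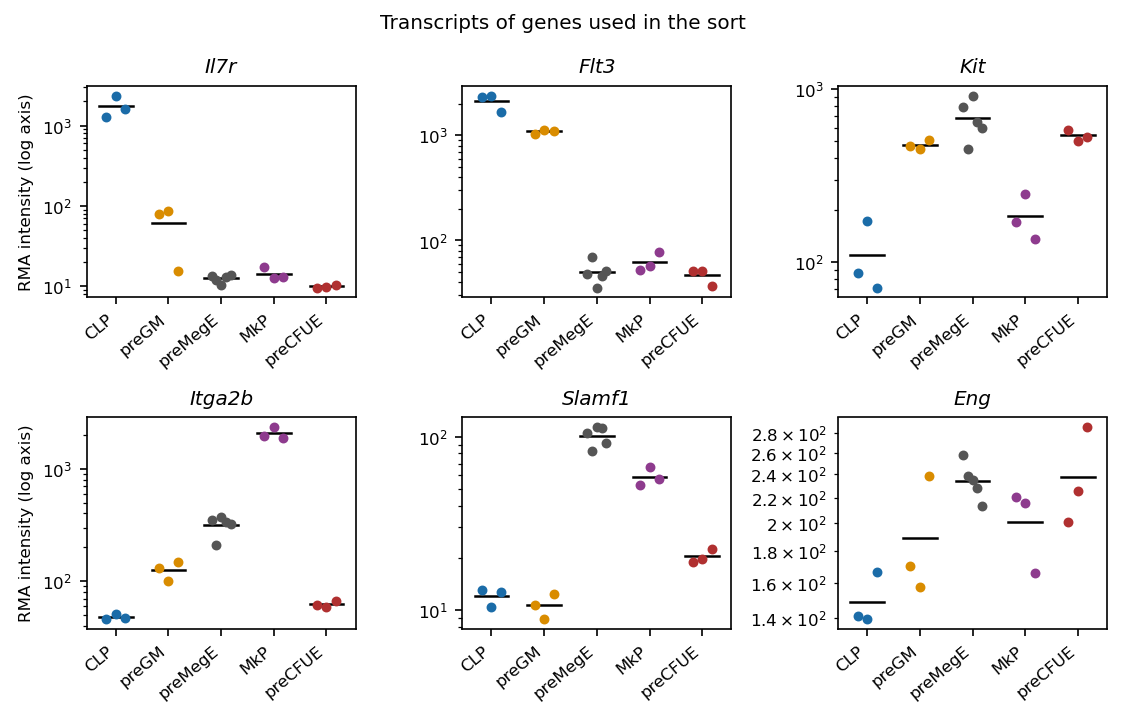
Intensity (log axis, RMA units) of 6 genes used in the sort (Il7r, Flt3, Kit, Itga2b, Slamf1 and Eng), 1 panel per gene, with each point an array and each bar the mean of a fraction. Itga2b stands at 2058 ± 249 in MkP against 319 ± 64.2 in preMegE (SD, n = 3 and 5), while Eng overlaps between preCFUE and preMegE.

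The preMegE and preGM gates differ in Slamf1, and this pair addresses the split between granulocyte or monocyte and megakaryocyte or erythroid potential. Genes of granules and monocytes were among the largest falls in preMegE. Mpo, which encodes myeloperoxidase, was 68.1 ± 59.8 in preMegE and 7503 ± 923 in preGM (log2 fold change -6.71 ± 0.41, adjusted p = 3.78e-08). The serine protease genes Ctsg and Prtn3 fell by 6.03 and 5.05 on the log2 scale, and Irf8, a regulator of monocytes and dendritic cells, fell by 5.20. On the higher side, Mfsd2b, which encodes the sphingosine-1-phosphate exporter of red cells and platelets, was 982 ± 175 in preMegE and 20.6 ± 3.74 in preGM (log2 fold change 4.76 ± 0.13, adjusted p = 1.93e-11). Other large rises were those of St8sia6 (4.67 ± 0.27), Trib2 (4.46 ± 0.21), Zg16 (4.45 ± 0.25) and Aldh1a1 (4.31 ± 0.14). Dntt, Bex6 and BC035044 were among the largest falls, at -5.62 ± 0.22, -5.42 ± 0.31 and -5.38 ± 0.30. Of the 1581 genes past the test, the arrays of 1517 did not overlap between the fractions. Chance gives this in 3.57% of genes for 5 against 3 arrays. That share is for unselected genes, whereas these were selected by a test on the same arrays, so the separation is no further support.

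Of 23 granulocyte and monocyte genes, 20 fell and 3 did not pass (21 fell adjusted over the list alone), with camera adjusted p = 6.88e-38, adjusted p = 4.96e-05 with an estimated correlation. Csf2ra (-0.36 ± 0.14, adjusted p = 0.183) and Cst7 (-0.22 ± 0.23, adjusted p = 0.814) were among those that did not pass, and both passed with array weights (0.00769 and 0.0304). Of 25 erythroid genes, 16 rose and 9 did not pass (19 rose adjusted over the list alone), with camera adjusted p = 5.79e-30, adjusted p = 0.000189 with an estimated correlation. Ces2g (4.26 ± 0.18), the water channel gene Aqp1 (4.16 ± 0.24) and the carbonic anhydrase gene Car1 (4.08 ± 0.29) rose, while Gypc (0.014 ± 0.20) and Hebp1 (0.41 ± 0.15) did not pass, at adjusted p = 0.993 and 0.152. The sign for Gypc turned under median centring (-0.0058). Megakaryocyte and platelet genes moved both ways. Of 27, 9 rose, 4 fell and 14 did not pass (9 rose and 4 fell adjusted over the list alone), with camera adjusted p = 0.0283, adjusted p = 0.128 with an estimated correlation. Vwf rose by 2.12 and Gp5 by 1.86, while Selp fell by 2.67 and Plek by 1.78, and Mef2c (-0.17 ± 0.20, adjusted p = 0.845) did not pass. That list call ended without preGM replicate 1 (adjusted p = 0.0638), preGM replicate 3 (0.0518) or preMegE replicate 3 (0.051), with array weights (0.0711) and among genes above the 40th percentile of mean level (0.0567). Of 22 myeloerythroid regulators, 9 rose, 7 fell and 6 did not pass (10 rose and 7 fell adjusted over the list alone), with no call for the list (camera adjusted p = 0.203, adjusted p = 0.604 with an estimated correlation). Klf1 (3.85 ± 0.21) and Gata1 (3.54 ± 0.15), the central erythroid transcription factors, rose and Gfi1 (-3.14 ± 0.26) fell, whereas Lmo2 (-0.11 ± 0.37) and Ikzf1 (0.17 ± 0.14) did not pass. The sign for Lmo2 turned with the 3-prime over 5-prime ratio as a covariate (0.061).

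Among stem or multipotent genes, of 23, 3 rose, 9 fell and 11 did not pass (3 rose and 11 fell adjusted over the list alone), with camera adjusted p = 3.53e-05, adjusted p = 0.00382 with an estimated correlation. Cd34 was 42.7 ± 7.84 in preMegE against 1878 ± 410.3 in preGM, and Hlf was 32.1 ± 5.00 against 304 ± 20.9. Of 20 cytokine receptor genes, 3 rose, 8 fell and 9 did not pass (3 rose and 11 fell adjusted over the list alone), with camera adjusted p = 1.02e-05, adjusted p = 0.0251 with an estimated correlation. Csf1r, the macrophage colony-stimulating factor receptor gene, fell by 4.67 and Il6ra by 3.50. Lymphoid genes were at a median of -0.048 and a mean of -0.73, and of 28, 1 rose, 8 fell and 19 did not pass (1 rose and 11 fell adjusted over the list alone), with camera adjusted p = 0.00208, adjusted p = 0.0709 with an estimated correlation. Dntt was 21.0 ± 4.79 in preMegE and 1866 ± 615 in preGM, and Ighm was 129 ± 254 and 904 ± 102, with preMegE replicate 5 at 583 for Ighm. Among 6 MHC class II genes, 4 fell and 2 did not pass (4 fell adjusted over the list alone), with camera adjusted p = 0.000329, adjusted p = 0.0502 with an estimated correlation, and H2-Aa fell by 1.58. Heme and iron genes moved both ways, and of 17, 4 rose, 2 fell and 11 did not pass (6 rose and 2 fell adjusted over the list alone), with camera adjusted p = 0.00672, adjusted p = 0.396 with an estimated correlation. Slc11a2, an iron transporter gene, rose by 1.40 and Alas1 fell by 2.06, and the list call ended without preGM replicate 3 (adjusted p = 0.0657) and with array weights (0.0569). Of 19 S phase genes, 7 fell and 12 did not pass (9 fell adjusted over the list alone), with camera adjusted p = 8.63e-07, adjusted p = 0.128 with an estimated correlation, and Rrm2 fell by 1.14 and Cdt1 by 0.97. Of 19 G2 and M phase genes, 1 fell and 18 did not pass (1 fell adjusted over the list alone), with camera adjusted p = 0.00751, adjusted p = 0.5 with an estimated correlation. The G2 and M phase call ended among genes above the 40th percentile of mean level (adjusted p = 0.0567). Among the sort genes, Flt3 (-4.09 ± 0.16), Fcgr3 (-0.71 ± 0.092) and Il7r (-1.25 ± 0.30) fell and Slamf1 (2.13 ± 0.094) and Itga2b (1.22 ± 0.16) rose, without a call for the 8 genes (camera adjusted p = 0.852, adjusted p = 0.877 with an estimated correlation). The Il7r call was lost without preGM replicate 1 (adjusted p = 0.0987) or preGM replicate 2 (0.103). It was also lost with the mean over probe sets (adjusted p = 0.0889) and in a fit of only these arrays (0.08). In all, 511 genes were higher and 1070 lower in preMegE, and 257 and 530 of these by at least 2-fold.

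**Figure D3:**
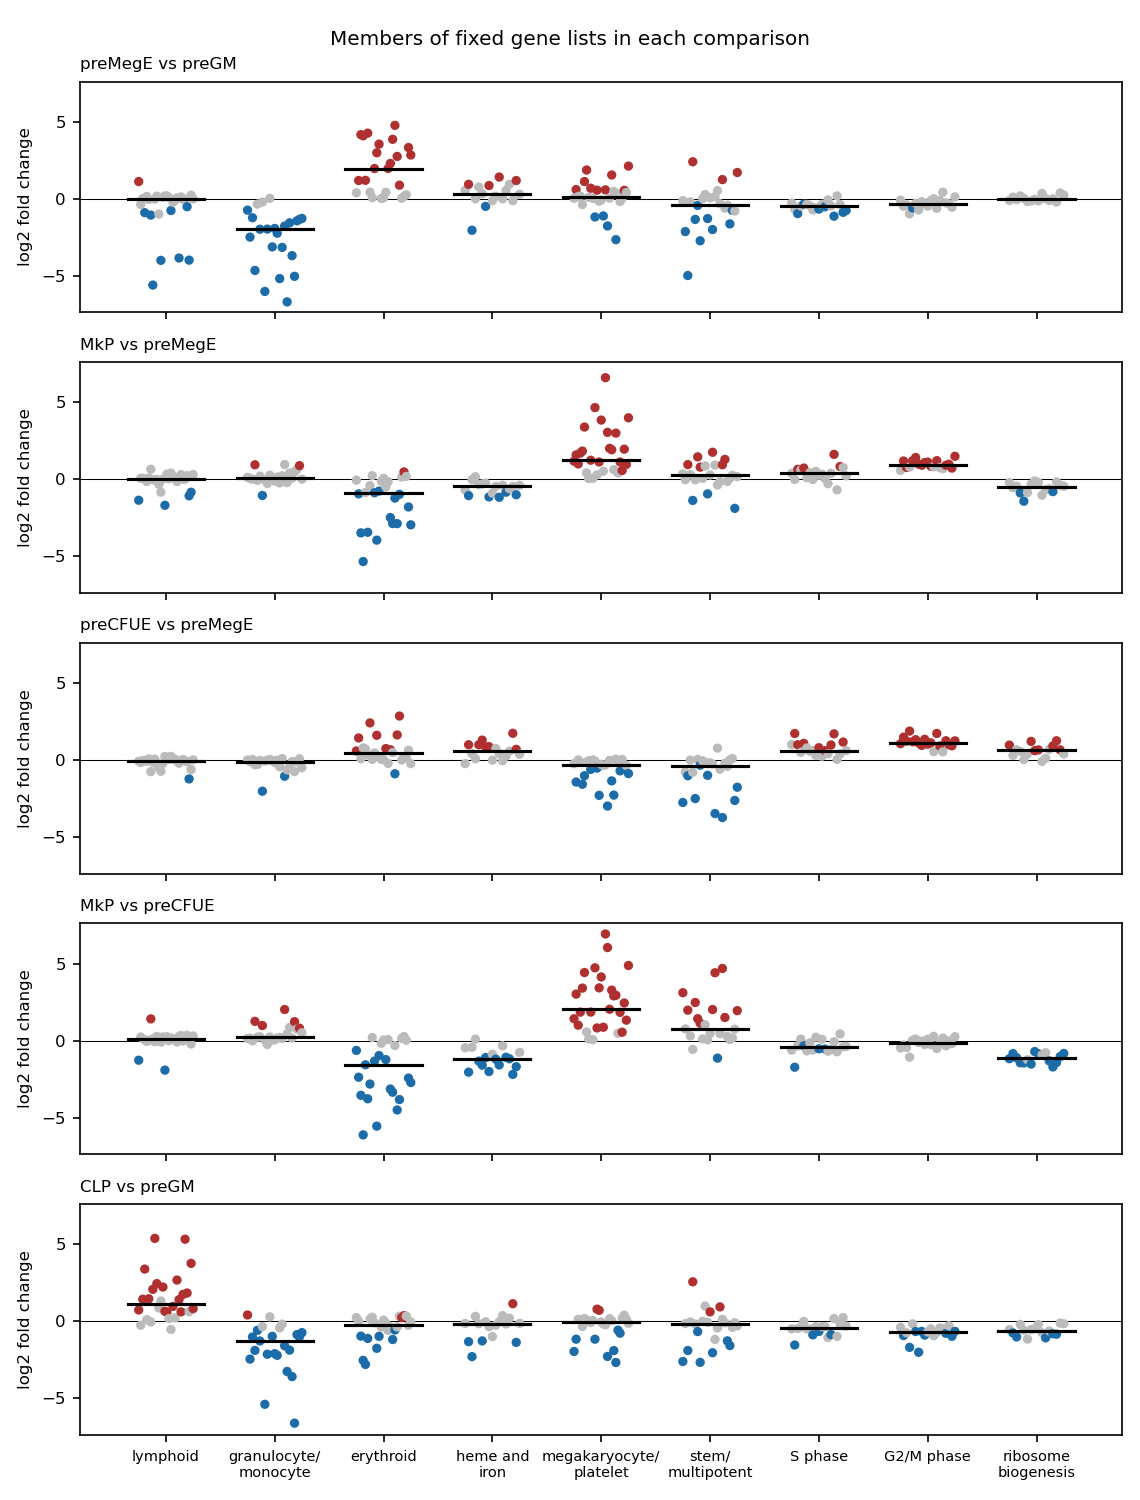
Log2 fold change (log2(intensity + 16) scale) of the genes of 9 lists, 1 panel per comparison, with each point a gene, red for past the test and higher, blue for past and lower, grey for not past, and each bar the list median. The granulocyte and monocyte median is -1.98 and the erythroid median 1.96 in preMegE against preGM, and the megakaryocyte and platelet median is 1.24 in MkP against preMegE.

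MkP against preMegE follows the candidate step from the shared precursor to the megakaryocyte branch. Pf4, which encodes platelet factor 4, rose from 50.9 ± 10.0 to 6431 ± 316 (log2 fold change 6.60 ± 0.16, adjusted p = 8.91e-12). Itgb3, the integrin chain that pairs with Itga2b, was 771 ± 119 in MkP and 15.1 ± 2.56 in preMegE (log2 fold change 4.66 ± 0.15, adjusted p = 1.48e-10). Vwf (4.00 ± 0.21), Mmrn1 (3.85 ± 0.11) and Slc35d3 (4.20 ± 0.22), which acts in platelet granules, completed the largest rises. The largest falls were those of Trib2 (-5.50 ± 0.21), Car1 (-5.34 ± 0.29), Lgals1 (-4.85 ± 0.29), Scin (-4.25 ± 0.19) and St8sia6 (-4.11 ± 0.27). Itga2b rose by 2.65, Kit fell by 1.79 and Slamf1 by 0.65. The sort genes as a list were not called (camera adjusted p = 0.754, adjusted p = 0.798 with an estimated correlation).

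Of 27 megakaryocyte and platelet genes, 20 rose and 7 did not pass (23 rose adjusted over the list alone), with camera adjusted p = 2.69e-33, adjusted p = 4.69e-06 with an estimated correlation. Slc2a3 (0.41 ± 0.14, adjusted p = 0.087) and Rgs18 (0.62 ± 0.33, adjusted p = 0.264) did not pass. Slc2a3 passed under quantile normalization (0.70, adjusted p = 0.0158), with the mean over probe sets (0.32, 0.00839), with array weights (0.43, 0.028) and without MkP replicate 2 (0.54, 0.0474). Rgs18 passed under quantile normalization (0.88, adjusted p = 0.0442), in a fit of only these arrays (0.0368) and with the 3-prime over 5-prime ratio as a covariate (0.83, 0.0103). Of 25 erythroid genes, 1 rose, 14 fell and 10 did not pass (1 rose and 16 fell adjusted over the list alone), with camera adjusted p = 1.24e-12, adjusted p = 0.00497 with an estimated correlation. Ermap (-3.95 ± 0.33), Aqp1 (-3.48 ± 0.24) and Ces2g (-3.44 ± 0.18) fell, while Car2 (-0.86 ± 0.34, adjusted p = 0.129) and Gypc (-0.13 ± 0.20, adjusted p = 0.76) did not pass, and the sign for Gypc turned under quantile normalization (0.14). Car2 passed with the SD over mean filter (adjusted p = 0.0455), with array weights (0.0316), in a fit of only these arrays (0.0376) and without CLP replicate 2 (0.0414). Stem or multipotent genes moved both ways, and of 23, 6 rose, 3 fell and 14 did not pass (8 rose and 3 fell adjusted over the list alone), with camera adjusted p = 0.0165, adjusted p = 0.0659 with an estimated correlation. Mecom (1.76 ± 0.14) and Esam (1.46 ± 0.12) rose and Sox4 (-1.89 ± 0.28) fell, while Angpt1 (0.35 ± 0.40) did not pass. Of 22 myeloerythroid regulators, 2 rose, 10 fell and 10 did not pass (2 rose and 10 fell adjusted over the list alone), with camera adjusted p = 0.000329, adjusted p = 0.177 with an estimated correlation, and Fli1 rose by 1.83 while Klf1 fell by 2.87. Of 17 heme and iron genes, 5 fell and 12 did not pass (7 fell adjusted over the list alone), with camera adjusted p = 3.97e-05, adjusted p = 0.209 with an estimated correlation, and Slc11a2 fell by 1.17.

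Of 19 G2 and M phase genes, 14 rose and 5 did not pass (19 rose adjusted over the list alone), with camera adjusted p = 5.5e-13, adjusted p = 0.0887 with an estimated correlation. Ccna2, which encodes cyclin A2, was 1012 ± 59.8 in MkP and 373 ± 65.0 in preMegE, and Ube2c was 389 ± 113 and 127 ± 28.5. Of 19 S phase genes, 4 rose and 15 did not pass (5 rose adjusted over the list alone), with camera adjusted p = 0.000641, adjusted p = 0.301 with an estimated correlation, and Rrm2 rose by 1.62 and Tyms by 0.83. Among 16 ribosome biogenesis genes, 3 fell and 13 did not pass (6 fell adjusted over the list alone), with camera adjusted p = 7.88e-05, adjusted p = 0.315 with an estimated correlation, and Myc fell by 1.43. Among 13 interferon response genes, 4 fell and 9 did not pass (5 fell adjusted over the list alone), with camera adjusted p = 0.00185, adjusted p = 0.0847 with an estimated correlation, and Iigp1 fell by 2.48 and Ifit1 by 1.61. In all, 724 genes were higher and 1158 lower in MkP, 198 and 494 of them by at least 2-fold, and the total of 1882 became 1184 without MkP replicate 3. The share of higher genes was 38.5%, and under quantile normalization it was 56.4% (1109 higher and 857 lower).

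**Figure D4:**
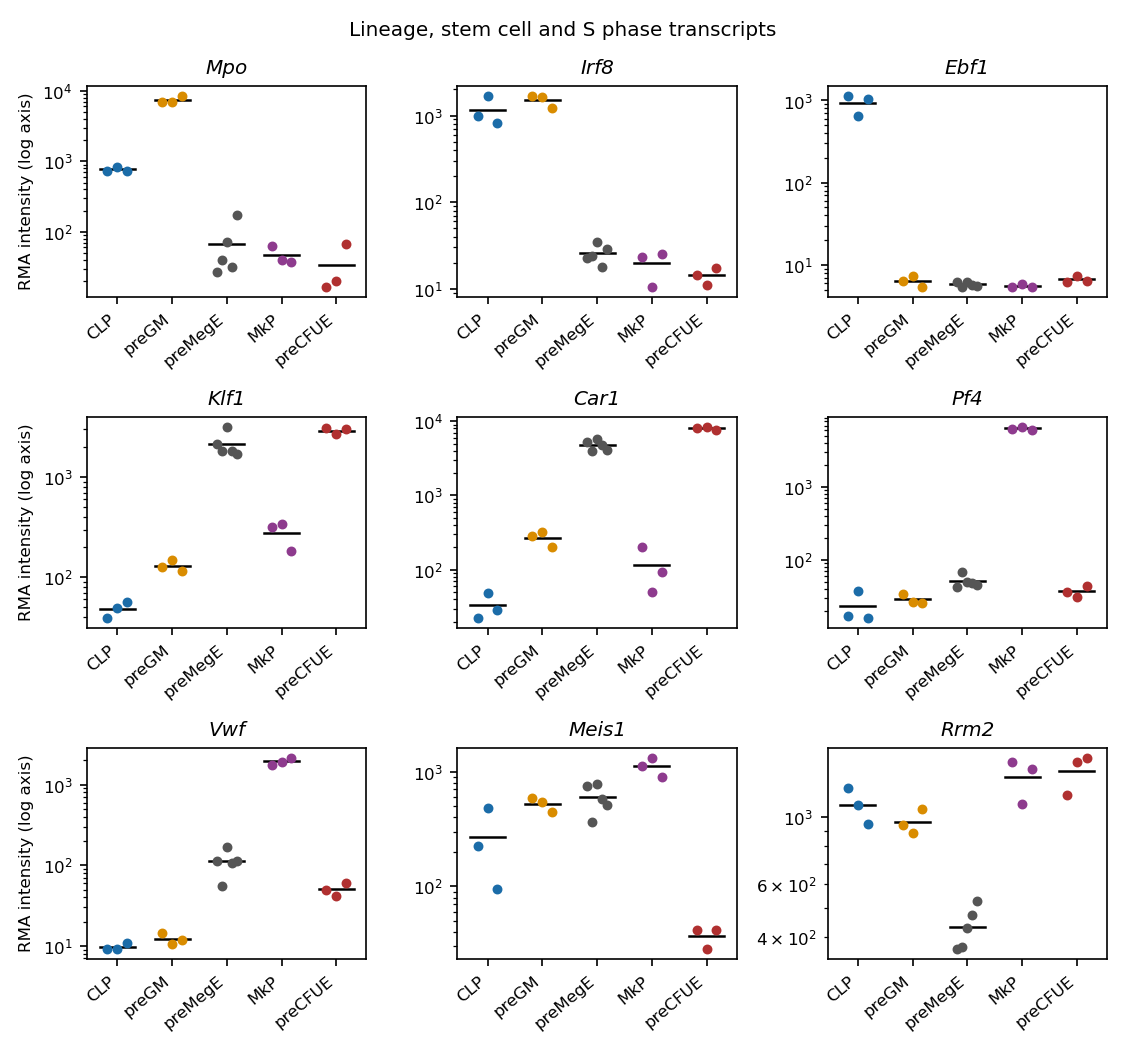
Intensity (log axis, RMA units) of Mpo, Irf8, Ebf1, Klf1, Car1, Pf4, Vwf, Meis1 and Rrm2, 1 panel per gene, with each point an array and each bar the mean of a fraction. Mpo is highest in preGM (7503 ± 923), Ebf1 in CLP (941 ± 262), Car1 in preCFUE (8109.5 ± 368) and Pf4 in MkP (6431 ± 316, all SD, n = 3).

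The preCFUE and preMegE gates differ in Eng, and their comparison follows the candidate step to the erythroid branch. Sphk1, which encodes a sphingosine kinase, was 692 ± 48.5 in preCFUE and 20.7 ± 4.05 in preMegE (log2 fold change 4.27 ± 0.14, adjusted p = 3.83e-10). The metallothionein gene Mt2 (3.55 ± 0.13), the blood group gene Rhd (2.85 ± 0.18), the asparagine synthetase gene Asns (2.74 ± 0.21) and the cyclin E1 gene Ccne1 (2.72 ± 0.23) also rose. Vim, which encodes the filament protein vimentin, was 139 ± 26.7 in preCFUE and 2167 ± 437 in preMegE (log2 fold change -3.81 ± 0.15, adjusted p = 2.48e-09). Other large falls were those of Ctla2a (-4.45 ± 0.27), Mycn (-3.74 ± 0.26), Limd2 (-3.68 ± 0.20) and Meis1 (-3.48 ± 0.36).

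Of 25 erythroid genes, 8 rose, 1 fell and 16 did not pass (10 rose and 1 fell adjusted over the list alone), with camera adjusted p = 3.09e-06, adjusted p = 0.0553 with an estimated correlation. Cldn13 (2.41 ± 0.18) and Rhag (1.62 ± 0.17) rose, while the abundant Car1 (0.78 ± 0.29, adjusted p = 0.135) and Car2 (0.71 ± 0.34, adjusted p = 0.284) did not pass. Car1 passed with the SD over mean filter (adjusted p = 0.0426), with array weights (0.0328), in a fit of only these arrays (0.00726), with the neutrophil marker mean as a covariate (0.98, 0.028) and without MkP replicate 1 (0.0325) or 2 (0.0493). Of 17 heme and iron genes, 7 rose and 10 did not pass (8 rose adjusted over the list alone), with camera adjusted p = 1.05e-05, adjusted p = 0.177 with an estimated correlation. The transferrin receptor gene Tfrc rose by 1.73 and Fech, which encodes the last enzyme of heme synthesis, by 1.29. Alas1 (0.41 ± 0.37, adjusted p = 0.749) did not pass. Of 19 G2 and M phase genes, 17 rose and 2 did not pass (17 rose adjusted over the list alone), with camera adjusted p = 4.35e-18, adjusted p = 0.0553 with an estimated correlation. Bub1 was 296 ± 9.97 in preCFUE and 73.1 ± 26.8 in preMegE, and Aurkb was 273 ± 22.2 and 89.0 ± 20.2. Kif20a rose by 1.72 and Cdk1 by 1.34, whereas Nusap1 (0.53 ± 0.28, adjusted p = 0.379) did not pass. Of 19 S phase genes, 8 rose and 11 did not pass (14 rose adjusted over the list alone), with camera adjusted p = 2.61e-10, adjusted p = 0.0709 with an estimated correlation. Rrm2 rose by 1.69, Uhrf1 by 1.16 and Fen1 by 1.07, while Mcm6 (0.24 ± 0.21) and Pcna (0.40 ± 0.47) did not pass, at adjusted p = 0.72 and 0.854. Among 16 ribosome biogenesis genes, 7 rose and 9 did not pass (10 rose adjusted over the list alone), with camera adjusted p = 4.83e-07, adjusted p = 0.209 with an estimated correlation, and Rrp12 rose by 1.25.

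Among stem or multipotent genes, of 23, 9 fell and 14 did not pass (1 rose and 10 fell adjusted over the list alone), with camera adjusted p = 6.11e-10, adjusted p = 0.000189 with an estimated correlation. Angpt1 (-2.76 ± 0.40) and Sox4 (-2.63 ± 0.28) fell, and Msi2 (-0.60 ± 0.25, adjusted p = 0.189) did not pass except with array weights (-0.74, 0.0411). Of 27 megakaryocyte and platelet genes, 12 fell and 15 did not pass (13 fell adjusted over the list alone), with camera adjusted p = 3.63e-12, adjusted p = 0.000294 with an estimated correlation, and Plek fell by 3.00 and Mef2c by 2.30. Of 22 myeloerythroid regulators, 7 fell and 15 did not pass (1 rose and 7 fell adjusted over the list alone), with camera adjusted p = 5.31e-05, adjusted p = 0.13 with an estimated correlation, and Erg fell by 2.51 and Gata2 by 2.47. Of 8 sort genes, 3 fell and 5 did not pass (3 fell adjusted over the list alone), with camera adjusted p = 0.000447, adjusted p = 0.0239 with an estimated correlation, and Itga2b fell by 2.07. Fcgr2b, at -0.47 ± 0.14, passed narrowly (adjusted p = 0.0461), and its call ended without preCFUE replicate 1 (adjusted p = 0.271), preCFUE replicate 3 (0.0968), any 1 preMegE array (0.0544 to 0.0912) or some arrays of the other fractions. It also ended in several other settings, among them quantile normalization (0.0841) and a trended and robust prior (0.125). Of 20 cytokine receptor genes, 4 fell and 16 did not pass (5 fell adjusted over the list alone), with camera adjusted p = 0.00648, adjusted p = 0.128 with an estimated correlation, and Tgfbr2 fell by 1.28. Of 23 granulocyte and monocyte genes, 2 fell and 21 did not pass (2 fell adjusted over the list alone), with camera adjusted p = 0.00678, adjusted p = 0.187 with an estimated correlation, and Cst7 fell by 2.03. Of 18 immediate-early genes, 2 fell and 16 did not pass (2 fell adjusted over the list alone), with camera adjusted p = 0.0312, adjusted p = 0.315 with an estimated correlation, and Ier3 fell by 1.37. That call ended without preMegE replicate 2 (adjusted p = 0.0677), preCFUE replicate 1 (0.0528) or preCFUE replicate 2 (0.101). It also ended under quantile normalization (0.106), with array weights (0.068) and with the 3-prime over 5-prime ratio (0.0697) or the neutrophil marker mean (0.0641) as a covariate. Of 10 markers of mast cells and basophils, 2 fell and 8 did not pass (2 fell adjusted over the list alone), with camera adjusted p = 0.024, adjusted p = 0.128 with an estimated correlation. The mast cell and basophil call ended without preMegE replicate 2 (adjusted p = 0.0756). Cpa3, a mast cell protease gene, was 25.9 ± 3.23 in preCFUE and 170.1 ± 36.4 in preMegE. In all, 865 genes were higher and 716 lower in preCFUE, and 266 and 340 of these by at least 2-fold.

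MkP against preCFUE sets the branches side by side. Pf4 was 6431 ± 316 in MkP and 37.2 ± 6.41 in preCFUE (log2 fold change 6.93 ± 0.18, adjusted p = 2.15e-11). Plek (6.05 ± 0.36), Cavin2 (5.41 ± 0.25), the actin-binding Tmsb4x (5.20 ± 0.20) and Vwf (4.88 ± 0.24) were the other largest rises. Car1 was 115 ± 76.7 in MkP and 8109.5 ± 368 in preCFUE (log2 fold change -6.13 ± 0.33, adjusted p = 1.15e-08). Ermap (-5.56 ± 0.37), Mt2 (-4.63 ± 0.15), Myh10 (-4.55 ± 0.24) and Rhag (-4.51 ± 0.19) were the other largest falls. Of the 2949 genes past the test, the arrays of 2915 did not overlap. For 3 against 3 arrays chance gives this in 10% of unselected genes, a share that does not apply to genes selected by the test.

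Of 27 megakaryocyte and platelet genes, 23 rose and 4 did not pass (24 rose adjusted over the list alone), with camera adjusted p = 1.51e-36, adjusted p = 4.69e-06 with an estimated correlation, and Itgb3 rose by 4.73. Gp5 (0.56 ± 0.30, adjusted p = 0.251) and Slc2a3 (0.48 ± 0.16, adjusted p = 0.0578) did not pass. Gp5 passed under quantile normalization (0.87, adjusted p = 0.0144). Slc2a3 passed under quantile normalization (0.88, adjusted p = 0.00594), with the mean over probe sets (0.31, 0.0126), with array weights (0.49, 0.0152) and without CLP replicate 3 (0.0347), preMegE replicate 2 (0.0418) or MkP replicate 2 (0.60, 0.0298). Of 25 erythroid genes, 17 fell and 8 did not pass (1 rose and 17 fell adjusted over the list alone), with camera adjusted p = 5.57e-15, adjusted p = 0.00309 with an estimated correlation, and Rhd fell by 3.83. Mfsd2b was 412 ± 74.2 in MkP and 514 ± 44.4 in preCFUE and did not pass (log2 fold change -0.32 ± 0.15, adjusted p = 0.179), and its sign turned under quantile normalization (0.095). Of 17 heme and iron genes, 11 fell and 6 did not pass (13 fell adjusted over the list alone), with camera adjusted p = 4.11e-09, adjusted p = 0.0847 with an estimated correlation. Tfrc (-2.20 ± 0.29), Alad (-2.05 ± 0.27), Glrx5 (-2.01 ± 0.25) and Urod (-1.69 ± 0.22) fell. Of 22 myeloerythroid regulators, 5 rose, 8 fell and 9 did not pass (6 rose and 9 fell adjusted over the list alone), with no call (camera adjusted p = 0.951, adjusted p = 0.979 with an estimated correlation), a median of 0.13 and a test statistic of the opposite sign. Fli1 (3.41 ± 0.33), Erg (2.48 ± 0.25) and Runx1 (2.04 ± 0.25) rose and Klf1 (-3.35 ± 0.23) fell, while Lmo2 (0.27 ± 0.41) did not pass. Of 23 stem or multipotent genes, 10 rose, 1 fell and 12 did not pass (15 rose and 1 fell adjusted over the list alone), with camera adjusted p = 3.46e-10, adjusted p = 0.000189 with an estimated correlation. Mycn was 1046 ± 205 in MkP and 24.7 ± 1.44 in preCFUE, and Meis1 was 1119 ± 209 and 37.2 ± 7.72.

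Of 16 ribosome biogenesis genes, 13 fell and 3 did not pass (15 fell adjusted over the list alone), with camera adjusted p = 2.53e-10, adjusted p = 0.128 with an estimated correlation, and Polr1b fell by 1.71 and Nolc1 by 1.52. Of 23 granulocyte and monocyte genes, 5 rose and 18 did not pass (6 rose adjusted over the list alone), with camera adjusted p = 0.000744, adjusted p = 0.116 with an estimated correlation, and Lyz2 rose by 2.02 and Csf1r by 1.25. Of 19 S phase genes, 4 fell and 15 did not pass (4 fell adjusted over the list alone), with camera adjusted p = 0.0444, adjusted p = 0.5 with an estimated correlation. The S phase call ended without MkP replicate 1 (adjusted p = 0.0541), 2 (0.0689) or 3 (0.0595), or preCFUE replicate 2 (0.0718) or 3 (0.0562). It also ended under quantile normalization (adjusted p = 0.755) and median centring (0.0888), among genes above the 40th percentile of mean level (0.213), without a pseudocount (0.0589) and with the 3-prime over 5-prime ratio (0.073) or the neutrophil marker mean (0.0511) as a covariate. Of 12 endothelial and stromal markers, 1 rose and 11 did not pass (1 rose adjusted over the list alone), with camera adjusted p = 0.0214, adjusted p = 0.301 with an estimated correlation. The gene that rose was Kdr (1.07 ± 0.15), and the endothelial call ended under quantile normalization (adjusted p = 0.125) and with the 3-prime over 5-prime ratio as a covariate (0.0645). Of 12 macrophage markers, 1 rose and 11 did not pass (1 rose adjusted over the list alone), with camera adjusted p = 0.0444, adjusted p = 0.315 with an estimated correlation. The gene that rose was Adgre1 (0.44 ± 0.10). The macrophage call ended without preGM replicate 3 (adjusted p = 0.0504), MkP replicate 1 (0.073), MkP replicate 3 (0.0544), preCFUE replicate 1 (0.0904) or preCFUE replicate 3 (0.0616). It also ended under quantile normalization (adjusted p = 0.245), among genes above the 40th percentile of mean level (0.384) and with the 3-prime over 5-prime ratio (0.0724) or the neutrophil marker mean (0.0574) as a covariate. Among the sort genes, Itga2b rose by 4.72 and Slamf1 by 1.03, and Kit fell by 1.51, without a call for the list (camera adjusted p = 0.0539, adjusted p = 0.15 with an estimated correlation). In all, 1003 genes were higher and 1946 lower in MkP, and the total of 2949 became 1894 without MkP replicate 3, 1782 without preCFUE replicate 1 and 1946 without preCFUE replicate 3. The share of higher genes was 34.0%, and under quantile normalization it was 52.9% (1311 higher and 1166 lower).

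CLP against preGM sets lymphoid against granulocyte or monocyte progenitors. Ebf1, a transcription factor gene of the B lineage, was 941 ± 262 in CLP and 6.29 ± 0.956 in preGM (log2 fold change 5.38 ± 0.14, adjusted p = 3.06e-11, and 2.45 as the mean over its probe sets). Rag1, which encodes part of the antigen receptor recombinase, was 1127 ± 756 and 8.78 ± 0.830 (log2 fold change 5.33 ± 0.28, adjusted p = 1.93e-08). Il7r (4.66 ± 0.33), Cmah (4.40 ± 0.22) and Mid1 (3.97 ± 0.42) also rose. Prtn3 (-6.62 ± 0.30), Ctsg (-5.39 ± 0.28), F13a1 (-5.39 ± 0.16) and Ccl9 (-4.90 ± 0.37) fell. Xist, the transcript that silences an X chromosome in female cells, was among the largest falls (log2 fold change -5.44 ± 0.33, adjusted p = 8.59e-08), at 26.6 ± 10.7 in CLP and 1030.4 to 3062 in the other 14 arrays. The Y-linked Eif2s3y was 43.5 to 329 in CLP and 4.72 to 8.25 elsewhere, and Kdm5d was 83.1 ± 38.3 in CLP and 5.72 to 8.22 elsewhere, while the dim Uty overlapped (10.1 to 18.3 in CLP and 7.44 to 12.4 elsewhere). As a list, the 4 sex-linked genes had a median of 1.10 and a mean of -0.18 with no call (camera adjusted p = 0.235, adjusted p = 0.347 with an estimated correlation). The labels do not give the sex of the mice, so sex and fraction cannot be told apart in this comparison. If the sexes differed, the CLP cells came from other mice, so mouse, sort and amplification could also differ with fraction.

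Of 28 lymphoid genes, 19 rose and 9 did not pass (22 rose and 1 fell adjusted over the list alone), with camera adjusted p = 5.3e-20, adjusted p = 8.97e-05 with an estimated correlation. The pre-B receptor gene Vpreb1 rose by 3.76 and the B cell adaptor gene Blnk by 3.39. Satb1 (0.62 ± 0.24, adjusted p = 0.0881) and Ighm (1.31 ± 0.85, adjusted p = 0.277) did not pass. Satb1 passed under quantile normalization (1.04, adjusted p = 0.00235), with the mean over probe sets (1.00, 3.05e-05) and with the 3-prime over 5-prime ratio as a covariate (0.81, 0.0371). Ighm passed without preMegE replicate 5 (adjusted p = 0.000749) and in a fit of only these 6 arrays (0.0412). Of 23 granulocyte and monocyte genes, 1 rose, 18 fell and 4 did not pass (2 rose and 18 fell adjusted over the list alone), with camera adjusted p = 3.03e-12, adjusted p = 0.00389 with an estimated correlation, and Ms4a6c fell by 3.60 and Mpo by 3.26. Irf8 was 1162 ± 472 in CLP and 1509 ± 238 in preGM and did not pass (log2 fold change -0.43 ± 0.24, adjusted p = 0.218). It passed without CLP replicate 2 (-0.74, adjusted p = 0.017) and with array weights (-0.61, adjusted p = 0.0381). Of 23 stem or multipotent genes, 3 rose, 7 fell and 13 did not pass (3 rose and 8 fell adjusted over the list alone), with camera adjusted p = 0.0252, adjusted p = 0.0821 with an estimated correlation. The stem gene call ended without CLP replicate 2 (adjusted p = 0.0656), under median centring (0.0888), quantile normalization (0.0516) and array weights (0.0645), with the mean over probe sets (0.0835) and among genes above the 40th percentile of mean level (0.587). Hlf (-2.67 ± 0.11) and Mecom (-2.04 ± 0.15) fell, while Hoxa9 (-0.067 ± 0.22) and Sox4 (-0.09 ± 0.31) did not pass, and both signs turned under quantile normalization (0.31 and 0.29). Another probe set of Sox4 passed the test in the opposite direction. Of 22 myeloerythroid regulators, 1 rose, 11 fell and 10 did not pass (1 rose and 11 fell adjusted over the list alone), with camera adjusted p = 3.97e-05, adjusted p = 0.128 with an estimated correlation, and Cebpa fell by 2.46 and Gata2 by 2.38. Among the sort genes, Flt3 rose by 0.93, Kit fell by 2.04, Itga2b by 1.14 and Fcgr3 by 0.80, without a call for the list (camera adjusted p = 0.396, adjusted p = 0.5 with an estimated correlation).

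The Gapdh 3-prime over 5-prime log2 ratio was 4.07 ± 1.06 in CLP and 3.27 ± 0.62 in preGM (SD, n = 3), beside the groups that follow. With the 3-prime over 5-prime ratio as a covariate, the list calls in this paragraph did not end. That fit takes a linear slope per gene, so it cannot exclude every effect of shortened RNA. Of 19 G2 and M phase genes, 9 fell and 10 did not pass (10 fell adjusted over the list alone), with camera adjusted p = 3.58e-05, adjusted p = 0.315 with an estimated correlation, and Ccnb2 fell by 2.01. Of 19 S phase genes, 4 fell and 15 did not pass (4 fell adjusted over the list alone), with camera adjusted p = 0.0228, adjusted p = 0.45 with an estimated correlation. The S phase call ended without CLP replicate 3 (adjusted p = 0.199), under quantile normalization (0.434), under median centring (0.0678) and among genes above the 40th percentile of mean level (0.349). The median of these S phase genes was -0.47, and -0.11 under quantile normalization. Of 16 ribosome biogenesis genes, 5 fell and 11 did not pass (9 fell adjusted over the list alone), with camera adjusted p = 0.00127, adjusted p = 0.402 with an estimated correlation. The ribosome biogenesis call ended under quantile normalization (adjusted p = 0.23) and among genes above the 40th percentile of mean level (0.0708). The median log2 fold change of all genes above that percentile was -0.296. In CLP replicate 2, with the lowest Gapdh ratio of the CLP arrays (3.00), the mean log2 value of these genes was 8.76. It was 8.68 to 8.99 in preGM, and 8.02 and 7.98 in CLP replicates 1 and 3. The S phase mean was 9.56 in CLP replicate 2, 9.44 to 9.68 in preGM, and 9.06 and 8.64 in CLP replicates 1 and 3. Of 13 interferon response genes, 4 fell and 9 did not pass (7 fell adjusted over the list alone), with camera adjusted p = 0.00236, adjusted p = 0.0896 with an estimated correlation. Oasl2 fell by 1.75, and the interferon call ended among genes above the 40th percentile of mean level (adjusted p = 0.0686). Of 18 immediate-early genes, 6 rose, 1 fell and 11 did not pass (6 rose and 1 fell adjusted over the list alone), with camera adjusted p = 0.00127, adjusted p = 0.138 with an estimated correlation. Fos was 1249 ± 992 in CLP (log2 fold change 3.51 ± 0.44, adjusted p = 0.000129), with its arrays far apart. Of 14 markers of T and NK cells, 3 rose and 11 did not pass (3 rose adjusted over the list alone), with camera adjusted p = 0.00226, adjusted p = 0.063 with an estimated correlation. Klrd1 rose by 1.31, a call that ended in a fit of only these 6 arrays (adjusted p = 0.0534). Of 9 markers of mature B and plasma cells, 2 rose and 7 did not pass (2 rose adjusted over the list alone), with camera adjusted p = 0.0214, adjusted p = 0.0847 with an estimated correlation, and Bank1 rose by 2.01. The call for the B and plasma cell list ended without CLP replicate 2 (adjusted p = 0.0804) and under quantile normalization (0.0758). Of 8 dendritic cell markers, 3 rose and 5 did not pass (3 rose adjusted over the list alone), with camera adjusted p = 0.00161, adjusted p = 0.0847 with an estimated correlation, and Ccr9 was 209.7 ± 44.5 in CLP and 9.40 ± 1.17 in preGM.

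In all, 923 genes were higher and 2414 lower in CLP, with 176 and 1098 of them at least 2-fold. Of these 3337 genes, the arrays of 2794 did not overlap between CLP and preGM. The model took the same spread per gene in each fraction, while CLP arrays correlated least with each other. Adjusted p-values of this comparison may therefore be too low. The total of 3337 became 1702 without CLP replicate 1, 6032 without CLP replicate 2, 1450 without CLP replicate 3, 1437 without preGM replicate 1, 1426 without preGM replicate 2, and 557 in a fit of only these 6 arrays. The share of higher genes was 27.7%, against 43.4% under quantile normalization (996 higher and 1300 lower) and 15.9% with each array centred on its median (543 higher and 2873 lower).

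Markers of cells outside the gates were tested in each comparison. None of the 12 neutrophil markers passed limma's test in any comparison, and the numbers at an unadjusted p under 0.05 were 0, 2, 0, 1 and 2 in the order above. The neutrophil list was not called (camera adjusted p = 0.57, 0.728, 0.122, 0.135 and 0.203), with a median of -0.75 in CLP against preGM. Its levels varied within fractions, and Ngp was 332 ± 284 in preGM, 284 ± 229 in preMegE, 385 ± 420.2 in MkP, 128 ± 43.2 in preCFUE and 48.6 ± 24.8 in CLP. None of the 5 eosinophil markers passed limma's test in any comparison (0 at an unadjusted p under 0.05), and camera adjusted p ran from 0.525 to 0.879. Of the listed markers, 1 of 14 for T and NK cells, 1 of 8 for dendritic cells and 1 of 7 for eosinophils stood on another list, and none of those for the other 5 cell groups did. Sharing was larger for 9 of 22 listed myeloerythroid regulators, 7 of 22 cytokine receptors and 7 of 26 granulocyte and monocyte genes. Results of those lists thus rest partly on the same genes as other lists. A mean over 100 in some fraction was reached by 3 markers of B and plasma cells, 1 of T and NK cells, 3 of neutrophils, 3 of mast cells and basophils, 2 of dendritic cells and 1 of endothelium and stroma. The Lin- gate should remove most of these cells when mature. Over the 120 list tests, camera called 53 at its preset correlation, and 14 of these held with an estimated correlation. The median, mean and test of a list differed in sign in 13 of the 120 tests, 0 of which were called.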

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

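The tests of how neutrophil markers vary together were chosen after the values were seen, and the one against the 3-prime over 5-prime ratio before, although the margin it had to clear was made stricter after its value was seen. Only preMegE has more than 3 arrays, and 12 of 153 values tested there had 1 array far from the other 4, where chance gives about 5%. In replicate 5, Ighm was 583 (others 10.8 to 22.0), Jchain 60.0 (7.61 to 10.7), Hebp1 57.8 (38.4 to 42.5), Mmp9 31.0 (14.5 to 17.8), and the mean log2 value of the mature B and plasma cell markers 5.77 (5.51 to 5.55). That list includes Jchain, so these flags are not separate. Jchain was tested here in addition to the named genes and the neutrophil markers. In replicate 3, Mycn was 965 (426 to 483), Vim 2935 (1845 to 2072), Zg16 771 (1153 to 1327) and the mean log2 value of the cytokine receptor genes 6.43 (6.27 to 6.31). In replicate 2, Fen1 was 2634 (2399.8 to 2456) and Itga2b 209 (324 to 376), and in replicate 1, Il6ra was 14.4 (11.5 to 12.3).

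Transcripts of neutrophil granules varied between arrays of the same fraction, and in preMegE replicate 5 S100a8 was 510.0 (highest other 197) and Ngp 627 (highest other 341), genes chosen after their values were seen. RNA amplification or degradation as a source was not settled: deviations of the marker mean and of the 3-prime over 5-prime ratio gave r = 0.116 (permutation p = 0.684, n = 17), a rank correlation of 0.230 and r = 0.261 without the 2 farthest arrays, and 17 arrays are too few to exclude a larger one (95% interval -0.465 to 0.627). Deviations of the 12 markers had a median pairwise correlation of 0.579 against at most 0.362 in 10000 random lists. Such lists hold genes drawn at random, so this shows that the markers vary together. It cannot tell whether the source is RNA of neutrophils or their late precursors in some samples. The correlation estimated by camera was 0.445 for the neutrophil markers, 0.468 for G2 and M phase genes and 0.521 for ribosome biogenesis genes. Not every marker followed: in preMegE replicate 2, the lowest for S100a8 (13.9), the dim Itgam (11.0) and Cxcr2 (17.8) were highest. The Lin- gate should remove mature neutrophils. A different make-up of the progenitors in those samples was not tested and stays open.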

How the results depend on the processing

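The fits without a pseudocount and with the 3-prime over 5-prime ratio or the neutrophil marker mean as covariates were chosen after the data were seen. Of 246 results for named genes, 189 passed the test, 158 passed in every setting that tested them and 0 of the 189 turned direction. Apart from the sort genes, the 189 were picked as the largest changes past the test in a comparison or list. Their steadiness was thus partly fixed by that choice and does not carry over to all genes past the test. The requirement of at least 2-fold change was applied to counts only. Over the settings other than leaving out 1 array, 64 calls of named genes ended and 36 new ones came. Calls of lists ended 71 times in those settings, 39 of them with an estimated correlation. Of the 189 log2 fold changes, 68 moved by over 1.5 times in some setting: 56 with the mean over probe sets, which averages in other probe sets, 8 without a pseudocount, 6 under quantile normalization, and 2 each without CLP replicate 3 or preCFUE replicate 1. Over all settings Ebf1 (CLP against preGM) ran from 2.45 to 7.19, Trib2 (preMegE against preGM) from 1.62 to 4.85, Mycn (preCFUE against preMegE) from -4.42 to -1.20 and Mmrn1 (MkP against preMegE) from 1.93 to 4.83. Where no cause is named below, the cause was not tested. Dim signals limit the array, as 47.3% of values lay under 16.

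Counts of genes past the test moved by over 1.5 times from 1581 (preMegE against preGM), 1882 (MkP against preMegE), 1581 (preCFUE against preMegE), 2949 (MkP against preCFUE), 3337 (CLP against preGM) and 6345 (F test). With the SD over mean filter, which tests fewer genes, they were 898 (MkP against preMegE), 770 (preCFUE against preMegE), 1164 (MkP against preCFUE), 1161 (CLP against preGM) and 1989 (F test). Over all probe sets, a larger number of tests, the probe sets past the test numbered 2829, 2406, 4529 (MkP and preCFUE each against preMegE, MkP against preCFUE) and 10663 (F test). With array weights, lowest for CLP replicate 2 and highest (5.52) for preGM replicate 2, the 6 counts were 3751, 3591, 3017, 4775, 6430 and 9748. A requirement of at least 2-fold left 787, 692, 606, 1319 and 1274 in the 5 comparisons. CLP against preGM gave 557 in a fit of only the groups compared, 2158 with the ratio covariate and 1450 with the neutrophil covariate. Fewer arrays alone do not explain the 557. With as many arrays, MkP against preCFUE rose from 2949 to 3587 genes in such a fit. Fits of only the groups compared gave 1529 (preMegE against preGM), 2524 (MkP against preMegE) and 2169 (preCFUE against preMegE). Only CLP against preGM fell far. The model of all arrays takes the same spread per gene in each fraction. Arrays of CLP correlated less with each other (0.940 to 0.960) than those of any other fraction (lowest 0.964, in preGM). The shared spread may thus be too small for CLP, and the adjusted p-values behind the 3337 genes too low. The part of this spread in the fall to 557 was not tested. Leaving out 1 array gave 1218 to 1753, 1184 to 2395, 1056 to 1868, 1782 to 3489, 1426 to 6032 and 5395 to 7810 in the order of the first sentence.

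With the replicate number as a block, the counts were 968 (MkP against preMegE), 906 (preCFUE against preMegE) and 1778 (CLP against preGM), and the signs of Msi2 (0.053, MkP against preMegE), Eng (-0.048) and Slc25a37 (0.042, both preCFUE against preMegE) turned. It ended 18 calls of named genes, among them Il7r in preMegE against preGM (adjusted p = 0.0592), and brought 1, Ighm in CLP against preGM (0.000861). The 30 pairs of arrays with the same number had a median correlation of deviations of -0.046, with 11 above 0.1, so a pairing by number was not visible. Pairs with different numbers ran from -0.601 to 0.594, so variation of another origin could hide a pairing, which is not excluded.

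Other signs that turned belonged to results past the test in neither setting. Median centring turned Gypc (-0.0058, preMegE against preGM) and Slamf1 (-0.011, CLP against preGM). Quantile normalization turned Eng (0.094), Gypc (0.14) and Msi2 (0.17) in MkP against preMegE, Eng (-0.072) in preCFUE against preMegE, Eng (0.17), Mfsd2b (0.095), Gypc (0.15) and Slc25a37 (0.011) in MkP against preCFUE, and Eng (0.16), Cst7 (0.11), Hoxa9 (0.31) and Sox4 (0.29) in CLP against preGM. The mean over probe sets turned Eng (-0.12, preCFUE against preMegE), Mfsd2b (0.055, MkP against preCFUE), Hoxa9 (0.15) and Sox4 (0.21, both CLP against preGM). Array weights turned Gypc (-0.049, preMegE against preGM) and Sox4 (0.00075, CLP against preGM). The ratio covariate turned Lmo2 (0.061, preMegE against preGM), Gypc (0.011, MkP against preCFUE), Hoxa9 (0.14) and Sox4 (0.000075, both CLP against preGM), and the neutrophil covariate turned Il7r (0.015) and Eng (-0.034) in preCFUE against preMegE. The test direction of the myeloerythroid regulators in MkP against preCFUE turned, with medians of 0.084 (median centring), 0.15 (quantile), 0.13 (40th percentile filter), 0.097 (mean over probe sets), 0.13 (only the groups compared), 0.13 (replicate block), 0.19 (no pseudocount) and 0.16 (ratio covariate). Leaving out 1 array gave Gypc -0.14 to 0.20 and Lmo2 -0.39 to 0.11 (preMegE against preGM), Gypc -0.38 to 0.00092 (MkP against preMegE), Flt3 -0.15 to 0.049, Eng -0.13 to 0.11, Slc25a37 -0.13 to 0.0043 and Hoxa5 -0.37 to 0.078 (preCFUE against preMegE), Hoxa9 -0.26 to 0.10 and Sox4 -0.36 to 0.088 (CLP against preGM), and regulator medians of 0.069 to 0.15.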

Other observations

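The tests for male donors, sex and fraction, mixing of preGM cells and an exchanged label were chosen after the result was seen, and the others before. The counts of genes shared by the branches, and the genes named in these first paragraphs, were also chosen after the values were seen. Some genes fell from preMegE to both MkP and preCFUE, among them Trp53inp1 (-3.19 and -3.24), Pdgfrb (-2.73 and -2.71), Rapgef3 (-3.05 and -2.54), Plac8 (-2.95 and -2.19) and Cpa3 (-2.02 and -2.13). Genes that rose in both included Rrm2 (1.62 and 1.69), Ccna2 (1.42 and 1.32), Ube2c (1.49 and 1.24), Incenp (1.39 and 1.18) and the focal adhesion gene Vcl (2.60 and 1.33). In all, 259 genes were lower and 104 higher in both fractions, and 185 moved in opposite directions. Both comparisons share the preMegE arrays, so their chance values are shared. With the preMegE arrays split between the comparisons, and so fewer arrays in each, a median of 133 genes (120 to 185 over 20 splits) were lower and 52 (38 to 68) higher in both, and 113.5 (100 to 217) moved in opposite directions. Independent lists of the sizes in those splits would share a median of 17.5, 11.0 and 28.3 genes of these kinds. Genes that moved in opposite directions exceeded this too, so the excess does not by itself show a shared direction. Over all genes the changes in both comparisons had a median correlation of 0.054 (-0.134 to 0.135 over the splits).

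Some lymphoid transcripts were also abundant in preGM, while others were near the floor there. Dntt was 7813 ± 2307 in CLP, 1866 ± 615 in preGM and 21.0 ± 4.79 in preMegE, and Notch1 was 2856 ± 194, 1101 ± 346 and 59.7 ± 14.1 (SD, n = 3, 3 and 5). In CLP and preGM, Rag1 was 1127 ± 756 and 8.78 ± 0.830, Ebf1 941 ± 262 and 6.29 ± 0.956, Ly6d 202 ± 33.3 and 17.8 ± 2.36, and Pou2af1 76.3 ± 48.4 and 9.14 ± 0.786 (SD, n = 3). Selp, which encodes P-selectin of platelets and endothelium, was 165 ± 14.0 in preGM and 212 ± 24.5 in MkP against 12.5 ± 1.47 in preMegE. Among immediate-early genes, Fos was 1249 in CLP and 75.5 in preGM and Jun 59.0 and 20.1, while Junb was 20.3 and 23.8.

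The CLP arrays stood apart from the other 14 in X- and Y-linked transcripts. Of the 4 sex-linked genes measured, 3 (Xist, Eif2s3y and Kdm5d) separated them and the dim Uty did not (10.1 to 18.3 against 7.44 to 12.4), which is consistent with the explanation that the CLP cells came from male mice and the other fractions from female mice. Genes on the X and Y chromosomes made up 3.91% of the genes past the test in CLP against preGM and 3.47% of those tested. This cannot tell how much of that difference comes from sex. With 626 such genes tested and 3195 autosomal genes past the test, they could not have made up most of it. Of the 626, 20.8% passed, against 18.4% of 17406 autosomal genes. Whether autosomal genes past the test in CLP against preGM differ because of sex cannot be told apart from the fraction, because 0 fractions had arrays of both kinds. The same limit holds for mouse, sort and amplification, since mice of another sex would be other mice.

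CLP replicate 2 correlated better with preGM arrays (0.961) than with the other CLP arrays (0.949). Against preGM cells in the CLP replicate 2 sample, the median share of the preGM level gained over Mpo, Prtn3, Ctsg and F13a1 was 0.144%, and at most 1.59%. Against a mislabelled preGM array, 5 of 5 genes (Rag1, Ebf1, Il7r, Vpreb1 and Blnk) were higher in this array than in every preGM array. With the slope on the 3-prime over 5-prime ratio removed, its own-fraction correlation exceeded that with preGM by 0.00540, from -0.0123 before, and 1 of 100 permuted ratios did as much, which is consistent with RNA amplification or degradation as a source. A true difference between the CLP samples stays open and was not tested.

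Other splits of the compared arrays, fitted on those arrays only, gave far fewer genes in 3 comparisons, which argues against a chance assignment of these arrays. The smallest share possible there was 1 of 56. As the arrays of a fraction may be technical repeats, the splits cannot address chance differences between mice or sorts. For preMegE against preGM, only the real split, 1 of 56, reached its 1529 genes (highest other 4). The same held for MkP against preMegE (1 of 56, with 2524 genes and a highest other of 1) and for preCFUE against preMegE (1 of 56, with 2169 and 0). Among 100 assignments of the 17 arrays to fractions, 1, the real one, reached the 6345 genes of the F test (highest other 643), with the same limit. The 10 splits of 3 against 3 arrays are too few for a share under 0.05: MkP against preCFUE gave 3587 genes (highest other 0) and CLP against preGM 557 (highest other 242), each with 1 split, the real one, as high.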
